A study of Mus musculus with 12 samples.

How the data were processed

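RNA of F9 mouse teratocarcinoma cells was measured on 12 Affymetrix mouse whole-genome arrays, 3 in each of 4 groups: wild type in vehicle (WT_vehicle), wild type in 1 µM RA (WT_RA), and the same with cells labelled as Rarg knockout (KO_vehicle, KO_RA), all for 24 h. The authors deposited MAS5 signal intensity values on a linear scale. The values show that the authors scaled each array so that the mean after trimming 2% of probe sets at each end was 500, and no further normalization between arrays was seen. The MAS5 version, masking and other steps are not stated. The deposited experiment files, of the kind other than expression values, hold the chip lot and the times of hybridization and scan as text, and were used only to find batches. Arrays with the same hybridization time were taken here as a fluidics run, and the wait before the scan was counted from that time. Nothing in the labels states whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, and replicate numbers follow the order of deposition.

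Of 45101 probe sets 64 controls were left out and 45037 were tested. In the annotation used, 34945 of these had 1 gene symbol, 932 several and 9160 none, which gave 18193 genes. Each gene was represented by its probe set with the highest mean log2 signal. The background level was set at the 95th percentile over 86 probe sets of olfactory, vomeronasal and taste receptors (signal 81.66, log2 6.61), and 22119 probe sets had a mean above it. Where a group's mean lay below this level, the change is given as at least the ratio of the brighter group's mean to the level. For arrays there is no read depth, and the number of arrays limits the precision.

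Signals were analysed as log2 of signal + 16 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend). The fit had 4 groups, 8 residual degrees of freedom and 5 contrasts: RA against vehicle in WT, the same in KO, the difference of these changes, and KO against WT in vehicle and in RA. Benjamini-Hochberg adjusted p values over all probe sets tested were held against 0.05. Choices of test, lists, rule for named genes and alternatives were made before the data were examined, except where stated. The rule named Rarg, the 8 genes with the largest rise and the 8 with the largest fall among called genes with no overlap between the arrays compared, up to 3 members of each list with the smallest adjusted p, all retinoid genes in the RA contrasts, and the 6 genes with the smallest p where none was called. Other probe sets of the named genes were checked, and none was called in the opposite direction. The text prints a part of the genes named by this rule, chosen after their values were seen with preference for those that kept their call when arrays were left out.

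The 26 gene lists cover retinoid metabolism and targets, Hox groups 1 to 5 and 6 to 13, Hox cofactors and Cdx genes, endoderm, basement membrane, pluripotency, neural and ectoderm, primitive streak and mesoderm, trophectoderm, G1 regulators, mitosis and replication, Wnt, TGF-beta with BMP and Nodal, FGF and ERK, imprinted genes, cholesterol synthesis, the secretory pathway, p53 targets, glycolysis and hypoxia, germ cells, markers of fibroblasts and muscle, of blood and of endothelium, ribosomal proteins and housekeeping genes. Of 651 symbols asked 604 were matched, 8 through an older name. Some genes stand in several lists. Tdgf1, Lefty2 and Bmp4 are in the pluripotency and TGF-beta lists and Fgf4 is in the pluripotency and FGF lists. Stra8 is in the retinoid and germ cell lists and Cdx1 in the retinoid and Hox cofactor lists. Results of lists with shared members are thus not separate. Lists were tested with limma's camera (preset correlation 0.01), with camera using an estimated correlation, and with fry. Camera compares a list's genes with all other genes, so its direction is relative to them. Fry tests whether a list's genes move one way on balance. Adjustment was over the lists of a contrast. Of the camera calls, 8 of 9 in RA against vehicle in WT, 0 of 5 in KO, 5 of 13 for the difference, 2 of 7 for KO against WT in vehicle and 0 of 13 in RA held with an estimated correlation. With the run as a block as well, 1, 0, 2, 1 and 0 lists passed in this order.

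The share of the wild-type RA change seen in knockout was the ratio of the median changes, with genes called without 1 WT_vehicle and 1 WT_RA array and the wild-type change measured on the arrays left out, averaged over 9 combinations. Combinations with fewer than 5 genes gave no value.

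Alternatives were other pseudocounts (1 and 64), quantile normalization, centring each array on its median, only probe sets above background, no intensity trend, array weights, only the groups compared, the type of title code or the chip lot as a block, 1 value per gene, stricter thresholds and leaving out each array. After the data were seen, the fluidics run as a block (6 residual degrees of freedom) was added, alone and with KO_vehicle replicate 3 left out. The type of title code separates run 1 (letters) from runs 2 and 3 (numbers), so these blocks are not independent of each other. There were 3 runs of 4 arrays, 2 chip lots and 1 scan day. The scan day was thus not used as a block.

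The pipeline was tested on simulated data with the same design. Of changes of 1 on the log2 scale it recovered 51.5% for RA in WT, 49% for RA in KO, 13% for the difference, 48% for KO against WT in vehicle and 64% in RA. Of changes of 2 it recovered 92.5%, 71%, 90% and 92% for RA in WT, the difference, and KO against WT in vehicle and in RA. Unchanged probe sets made up 18 of 306, 2 of 52, 5 of 105, 11 of 149 and 24 of 389 calls in the order of the contrasts. A simulated share of 0.5 came back as 0.51.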

Results

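F9 cells are a mouse teratocarcinoma line whose stem cells turn into endoderm-like cells under retinoic acid (RA). RNA from wild-type F9 cells (WT) and from F9 cells labelled as knockout (KO) for the retinoic acid receptor gamma gene, Rarg, was measured after 24 h in 1 µM RA or in the ethanol vehicle. There were 12 arrays, 3 in each of the 4 groups, and their number limits the precision. KO below means arrays labelled knockout. The array median signal lay between 71.2 and 94.6 on 11 arrays and was 143 on KO_vehicle replicate 3. The arrays went through 3 fluidics runs of 4 arrays, each run with 1 array of every group, so values from each run and from a fit with the run as a block stand beside the results. Run 1 held the samples with a letter code in the title, and runs 2 and 3 those with a number code. What sets run 1 apart can therefore not be told apart from a difference between these sets of samples. Changes are log2 differences of signal + 16, with the standard error (SE) of limma's fit and n = 3 arrays per group.

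Rarg, the targeted gene, gave a signal of 1476 ± 292 (SD, n = 3) in WT_vehicle, 1243 ± 222 in WT_RA, 1636 ± 102 in KO_vehicle and 1357 ± 288 in KO_RA. The KO minus WT difference was 0.16 (SE 0.192, limma adjusted p = 0.733, with the run as a block 0.639) in vehicle and 0.12 (adjusted p = 0.885) in RA. In runs 1, 2 and 3 it was -0.25, 0.34 and 0.40 in vehicle and -0.51, 0.33 and 0.54 in RA. Without WT_RA replicate 2 the difference in RA was -0.01. The other Rarg probe set gave 0.09 and 0.39 (adjusted p = 0.861 and 0.378). In run 1 this probe set gave less in knockout than in wild type in vehicle (1033 against 1343) and more in RA (942 against 823). The mean Rarg signal was therefore not lower in the arrays labelled knockout, while in run 1 the brighter probe set was lower in both treatments. Where these probes lie relative to the disrupted part of the gene is not known here, so this signal checks neither genotype. Over bright probe sets, each of the 12 arrays correlated more with the arrays of its own genotype label than with those of the other.

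The comparison of RA with vehicle in wild-type cells asks which transcripts RA changed within 24 h. RA raised several classical retinoid targets strongly. Stra8, a retinoid-induced gene of germ cell meiosis, went from a signal of 1830 ± 382 to 11270 ± 2980, a change of 2.60 (SE 0.179, adjusted p = 2.68e-06, 2.49 to 2.70 within the runs). Rarb, which encodes another retinoic acid receptor, rose by 3.06 (SE 0.235, adjusted p = 3.64e-06, 2.99 to 3.14 within the runs). Cyp26a1, whose enzyme degrades RA, rose by 3.03 (SE 0.304, adjusted p = 6.71e-05, 2.77 to 3.46). Crabp2, a cellular RA-binding protein, rose by 3.30 (SE 0.379, adjusted p = 0.000285, 2.65 to 4.11). Of the 37 measured members of the list of retinoid metabolism and targets, 10 rose and 0 fell by limma (12 rose adjusted over the list alone), and Nrip1 rose by 2.17 (adjusted p = 4.28e-05). Stra6, the cellular retinol transporter, rose at least 5.41-fold over the background level (adjusted p = 0.00202) and Cyp26b1 at least 3.14-fold (adjusted p = 0.00294). The list as a whole moved up (camera adjusted p = 5.18e-09, 0.0295 with an estimated correlation, 8.87e-08 with the run as a block, 0.062 with both), with medians of 0.30, 0.45 and 0.46 in runs 1, 2 and 3.

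Hox genes at the 3' side of the clusters, which pattern the hindbrain and anterior trunk, rose with them. Of 13 measured Hox genes of paralog groups 1 to 5, 7 rose (10 adjusted over the list alone). Hoxa5 rose by 2.69 (SE 0.321, adjusted p = 0.000365, 2.50 to 3.00 within the runs), Hoxb2 at least 7.03-fold (adjusted p = 0.000165) and Hoxb5 at least 2.75-fold (adjusted p = 0.00108). Within the runs the list median was 2.98, 1.94 and 2.59, and the camera adjusted p was 8.7e-19 (0.0103 with an estimated correlation, 1.46e-14 blocked, 0.0133 with both). Of 14 measured Hox cofactors and Cdx genes 2 rose (5 rose and 1 fell adjusted over the list alone), among them Cdx1, a regulator of Hox genes, at least 5.16-fold (adjusted p = 0.00235). Hox genes of groups 6 to 13 did not pass as a list (camera adjusted p = 0.586). Outside the lists, Gpr50, an orphan relative of the melatonin receptors, rose at least 10.9-fold (adjusted p = 0.00184).

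RA lowered part of the stem cell programme in wild-type cells. Of 41 measured pluripotency genes, 8 fell and 0 rose (18 fell and 1 rose adjusted over the list alone). Tdgf1, a Nodal co-receptor, went from a signal of 11310 ± 945 to 3284 ± 105, a change of -1.78 (SE 0.132, adjusted p = 3.64e-06, -1.67 to -1.92 within the runs). Fgf4, a growth factor of pluripotent cells, fell by 1.34 (SE 0.158, adjusted p = 0.000341). The list moved down (camera adjusted p = 6.14e-13, 0.0169 with an estimated correlation, 8.79e-13 blocked, 0.0697 with both), with medians of -0.28, -0.39 and -0.35 in runs 1, 2 and 3. Of 24 measured genes of FGF and ERK signalling 4 fell (8 adjusted over the list alone), among them Spry4 by -1.84 (adjusted p = 6.71e-05), a feedback inhibitor of the pathway. That list moved down too (camera adjusted p = 5.02e-07, 0.0103 with an estimated correlation, 1.07e-06 blocked, 0.062 with both, medians -0.48, -0.31 and -0.33). Ntn1, which encodes the guidance cue netrin 1, fell by 2.48 (adjusted p = 5.76e-05), Myc by 1.97 (adjusted p = 0.000625), the neural and anterior regulator Otx2 by 1.69 (adjusted p = 0.000645) and Id3, an inhibitor of basic helix-loop-helix factors, by 1.64 (adjusted p = 0.000149).

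Endoderm genes did not pass as a group in wild-type cells at 24 h. Of 39 measured genes of primitive, parietal and visceral endoderm, 1 rose (1 adjusted over the list alone) and the list gave a camera adjusted p = 0.499. The 1 gene was Foxa1, a pioneer transcription factor, up by 2.13 (SE 0.277, adjusted p = 0.000818, 2.06 to 2.24 within the runs). Of 29 measured basement membrane genes 0 passed by limma (0 adjusted over the list alone, camera adjusted p = 0.907). Glycolysis and hypoxia genes moved down as a list (1 of 23 fell, 6 adjusted over the list alone, camera adjusted p = 2.85e-07, 0.0301 with an estimated correlation, 0.101 with the run as a block as well). Cholesterol synthesis genes had a list median of -0.25 with 0 of 20 past the threshold singly (0 adjusted over the list alone, camera adjusted p = 0.000448, 0.0169 with an estimated correlation, 0.062 with both). Germ cell genes moved up (2 of 21 rose, 2 adjusted over the list alone, 0.001 and 0.0458, 0.123 with both), and Hox cofactors gave 6.16e-05 and 0.0169 (0.0674 with both). Of the list calls in wild type, Hox genes of groups 1 to 5 alone thus passed with the run as a block and an estimated correlation together. TGF-beta, BMP and Nodal genes had 4 of 38 members lower (6, with 1 higher, adjusted over the list alone), but the list's adjusted p of 0.0149 became 0.145 with an estimated correlation and 0.0736 with the run as a block, and was 0.0731 without WT_vehicle replicate 1 and 0.0994 without WT_RA replicate 3. The other 14 lists did not pass either, with camera adjusted p values of 0.065 for regulators of G1 and higher for trophectoderm (0.892), neural and ectoderm (0.746), primitive streak and mesoderm (0.0786), Wnt signalling (0.0729), imprinted genes (0.411), mitosis and replication (0.362), p53 targets (0.0951), the secretory pathway (0.746), ribosomal proteins (0.252), housekeeping genes (0.26) and the markers of fibroblasts and muscle (0.892), blood (0.875) and endothelium (0.411).

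In all, limma called 211 probe sets in wild-type cells, 124 up and 87 down (89 genes up and 61 down), and 949 with the run as a block (517 up and 432 down). The blocked fit kept all 211. The count rested on single arrays, falling to 84 without WT_RA replicate 2, 95 without WT_RA replicate 1, 121 without WT_vehicle replicate 2 and 123 without WT_vehicle replicate 1. It was 84 with arrays centred on their medians and 51 without the intensity trend.

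**Figure D1:**
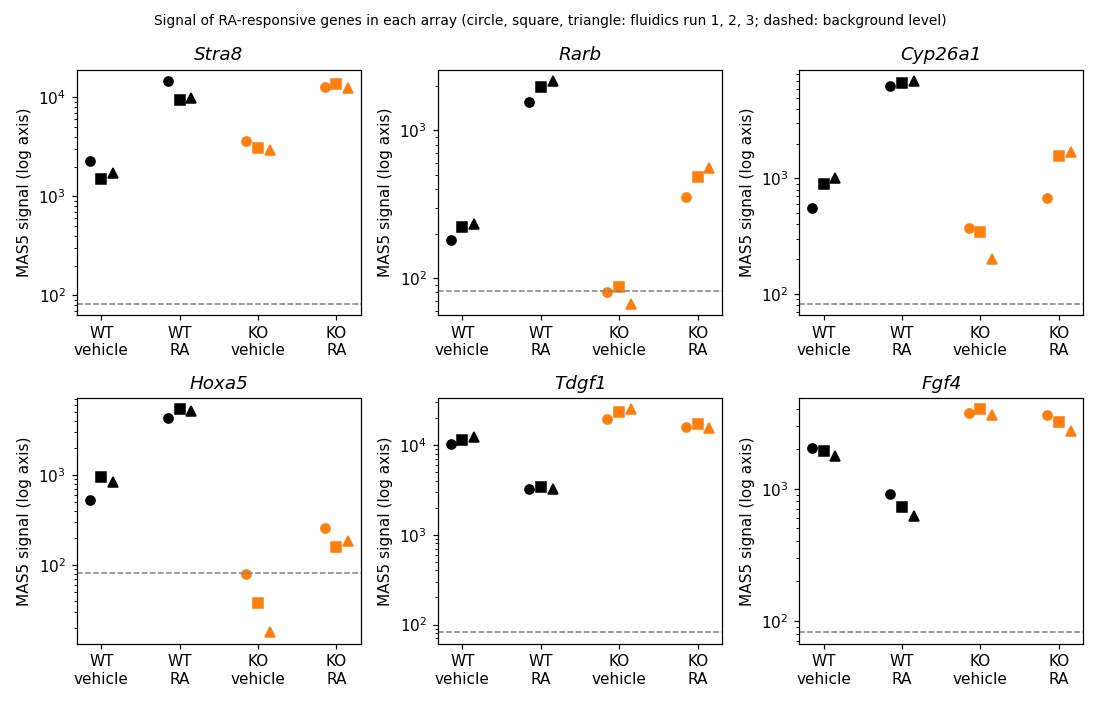
MAS5 signal (log axis) of Stra8, Rarb, Cyp26a1, Hoxa5, Tdgf1 and Fgf4 in each of the 12 arrays by group, with circles, squares and triangles for fluidics runs 1, 2 and 3 and a dashed line at the background level. Stra8 reached a mean of 11270 in WT_RA and 12970 in KO_RA, while Tdgf1 fell to 3284 in WT_RA and stood at 16120 in KO_RA.

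The same comparison in knockout cells asks which changes RA made in the arrays labelled knockout. Stra8 rose by 2.02 (SE 0.179, adjusted p = 4.99e-05, 1.83 to 2.14 within the runs) and reached 12970 ± 613, against 11270 ± 2980 in wild type. Foxa1 rose by 2.86 (SE 0.277, adjusted p = 9.27e-05, 2.31 to 3.66 within the runs), Nrip1 by 1.58 (SE 0.203, adjusted p = 0.00228, 1.38 to 1.78) and Rarb at least 4.84-fold (adjusted p = 0.000121). These 4 genes passed in every fit that left out 1 array. Cyp26a1 rose by 1.99 (SE 0.304, adjusted p = 0.0129), with 0.84 in run 1, 2.15 in run 2 and 2.97 in run 3. It lost its call without KO_RA replicate 1 (1.80, adjusted p = 0.117), without KO_vehicle replicate 2 (1.73, adjusted p = 0.119) and without KO_RA replicate 2 (1.75, adjusted p = 0.118). Of the 37 retinoid genes 5 rose (8 adjusted over the list alone), and the list moved up (camera adjusted p = 7.5e-05, 6.86e-05 blocked). With an estimated correlation its adjusted p was 0.374, and its medians in runs 1, 2 and 3 were -0.01, 0.42 and 0.43.

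Few stem cell and Hox genes passed in knockout cells. Of the 41 pluripotency genes 0 were called by limma (4 up and 3 down adjusted over the list alone, camera adjusted p = 0.113, 0.0292 blocked). The list medians in runs 1, 2 and 3 were 0.03, -0.26 and -0.31, against -0.28, -0.39 and -0.35 in wild type, and without KO_vehicle replicate 3 the list was called downwards (7.18e-06). Tdgf1 changed from 22420 ± 2870 to 16120 ± 689, a difference of -0.47 (adjusted p = 0.479), and Spry4 had -0.98 (adjusted p = 0.0602). Of 13 Hox genes of groups 1 to 5, 1 rose (4 adjusted over the list alone, list median 0.28). The camera adjusted p was 0.0109 (0.0183 blocked) and 0.441 with an estimated correlation, and the medians in runs 1, 2 and 3 were 0.01, 0.58 and 0.12. The camera call ended without KO_vehicle replicate 1 (0.061), KO_vehicle replicate 2 (0.0555) and KO_RA replicate 3 (0.223). Secretory pathway genes (7.5e-05, 0.249 with an estimated correlation), basement membrane genes (0.00482 and 0.633) and germ cell genes (0.0298 and 0.377) had list shifts upwards with 0, 0 and 2 called members. Without KO_vehicle replicate 3 the first gave 0.0897 and basement membrane genes turned to a downward shift at 0.625. The latter also lost the call without KO_RA replicate 1 (0.178) or KO_RA replicate 2 (0.266), and germ cell genes without KO_vehicle replicate 1 (0.0595), KO_vehicle replicate 2 (0.155) or KO_RA replicate 3 (0.101).

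Limma called 36 probe sets in knockout cells, 34 up and 2 down (25 genes up and 2 down), and 136 with the run as a block, which kept all 36. The count fell to 13 without KO_RA replicate 1 or KO_RA replicate 2, to 18 without KO_vehicle replicate 2 and to 22 without KO_vehicle replicate 1, and was 55 without WT_vehicle replicate 3. Without KO_vehicle replicate 1, 3 of the 5 list calls were kept. Without KO_vehicle replicate 3, 3 were kept and 4 lists were gained, all downwards: pluripotency (camera adjusted p = 7.18e-06), FGF with ERK (0.0178), G1 regulators (0.0178) and p53 targets (0.0217).

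Whether RA acted differently in the 2 genotypes is the test of the difference between the RA changes. In tests of whole lists, pluripotency genes differed upwards and Hox genes of groups 1 to 5 downwards, while 0 single probe sets passed by limma, with 2084 at an unadjusted p under 0.05, where 2252 of 45037 would lie there if none differed. Tdgf1 had the smallest p, with a difference of 1.31 (SE 0.187, 1.40, 1.29 and 1.24 in runs 1, 2 and 3), but its adjusted p was 0.0782. Gpr50 had 0.0782 as well. Neither passed in the fit over 4 groups, and both passed with the run as a block (adjusted p = 0.00188 for Tdgf1 and 0.00761 for Gpr50). Fgf4 had a difference of 1.09 (adjusted p = 0.481, 0.0116 blocked), Sfrp5, a secreted Wnt antagonist, -2.59 (0.391, 0.0269 blocked), and the transcription factor Sox4 -1.02 (0.481, 0.036 blocked). With the run as a block 22 probe sets passed (10 up and 12 down). With KO_vehicle replicate 3 left out as well 2 passed, with adjusted p values of 0.0228 for Tdgf1 and 0.0244 for Gpr50, and of 0.0728 for Fgf4, 0.134 for Sfrp5 and 0.175 for Sox4, whose differences of 0.99, -2.34 and -0.96 kept their direction. In the fit over 4 groups 1 each passed without WT_vehicle replicate 3 and without KO_vehicle replicate 3. Of the 150 genes called in wild type 0 also passed this test. In the fit with the run as a block, 13 of the genes which that fit called in wild type (327 raised and 283 lowered) passed it. In simulated data the same fit recovered 13% of differences of 1 on the log2 scale and 71% of differences of 2, so a count of 0 leaves many differences of such a size unseen.

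As lists, Hox genes of groups 1 to 5 differed with a median of -1.51 (0 members called, 5 lower adjusted over the list alone, camera adjusted p = 1.43e-10, 0.0324 with an estimated correlation, 3.97e-09 blocked, medians -2.04, -1.62 and -1.49 in runs 1, 2 and 3). Pluripotency genes differed upwards with a median of 0.29 (0 called, 5 higher adjusted over the list alone, 1.35e-09, 0.0324 with an estimated correlation, 3.37e-10 blocked, medians 0.45, 0.22 and 0.08). So did genes of FGF and ERK signalling, with a median of 0.27 (0 called, 4 adjusted over the list alone, 0.000236, 0.0324 with an estimated correlation, medians 0.48, 0.22 and 0.11), cholesterol synthesis with 0.33 (0 called, 0 adjusted over the list alone, 9.17e-06, 0.0198 with an estimated correlation, medians 0.36, 0.28 and 0.24) and glycolysis with 0.36 (0 called, 0 adjusted over the list alone, 2.07e-07, 0.0381 with an estimated correlation, medians 0.57, 0.26 and 0.20). With the run as a block and an estimated correlation, adjusted p values under 0.05 remained for Hox genes of groups 1 to 5 and for cholesterol synthesis (both 0.0282). Without KO_vehicle replicate 3, 7 of the 13 list calls were kept, 6 ended and Wnt signalling was gained downwards (0.0187).

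Across the genes called in wild type, the knockout change went the same way for 83 of 89 raised and 59 of 61 lowered genes. It was smaller for 77 and 61 of them, counts that selection on the wild-type change inflates. Selected the other way, of 25 genes called up in knockout 13 had the larger change in knockout (40 of 74 with the run as a block). Measured on wild-type arrays not used to select the genes, the knockout showed a share of 0.508 of the wild-type change (SD 0.057, 0.411 to 0.614 over 9 ways of leaving out 1 WT_vehicle and 1 WT_RA array, 26 to 93 genes), with medians of 0.86 against 1.67. The share was 0.423 with the run as a block, over other genes (218 to 564, with a wild-type median of 0.88), and 0.779 without WT_RA replicate 2 and 0.761 without WT_vehicle replicate 3. In runs 1, 2 and 3 the raised genes had medians of 1.43, 1.48 and 1.56 in wild type and 0.54, 0.80 and 0.87 in knockout. The lowered genes had -1.12, -1.09 and -1.22 against -0.23, -0.49 and -0.47. Called lists shared 21 raised genes, where 0.122 would be shared by independent lists, and 1 lowered gene, Ntn1. Across 12254 genes, which are not independent replicates, Pearson's r of the RA changes was 0.212 and Spearman's rho 0.22. Without KO_vehicle replicate 1, r was 0.136.

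**Figure D2:**
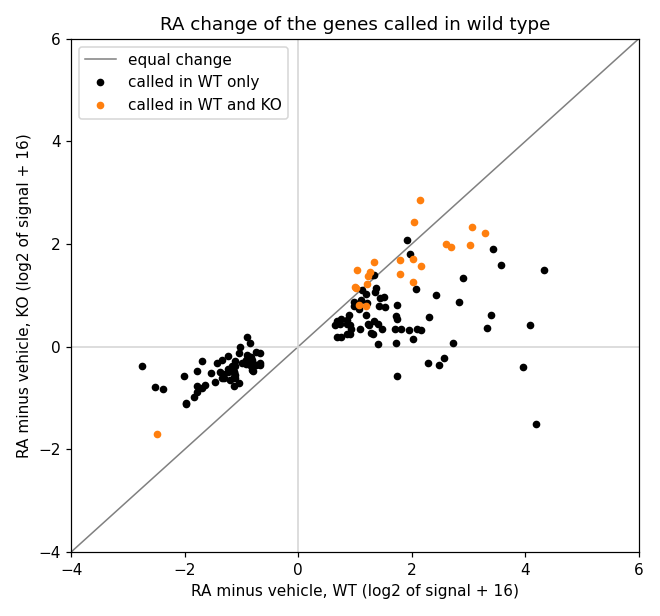
RA minus vehicle in wild type (horizontal) against knockout (vertical), both in log2 of signal + 16, for the 150 genes called in wild type, with the 22 also called in knockout in their own colour and a grey line of equal change. Among raised genes 77 of 89 had the smaller change in knockout, a count that selection in wild type inflates.

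The comparison of knockout with wild type in vehicle asks how the cells differed without added RA. Many endoderm genes were far lower in knockout. Of 39 measured endoderm genes 21 were lower and 1 higher (24 and 2 adjusted over the list alone), with list medians of -1.39, -1.53 and -1.45 in runs 1, 2 and 3 (camera adjusted p = 3.76e-18, 0.0385 with an estimated correlation, 4.55e-19 blocked, 0.12 with both). Dab2, an endocytic adaptor of visceral endoderm, was lower by -3.82 (SE 0.740, adjusted p = 0.00562), by -2.86 and -2.71 in runs 2 and 3, and in run 1 its signal was 124.4 against 8214 in wild type. Pdgfra, a receptor of primitive endoderm, was lower by -3.94 (adjusted p = 4.17e-05), with -3.28 in run 2 and -3.45 in run 3, while in run 1 its knockout signal of 49.57 lay below the background level of 81.66. Without KO_vehicle replicate 3 its difference was -3.42 (adjusted p = 0.000409). Apoe, Krt8 and Fabp3 had -2.59, -2.20 and -2.62 (adjusted p = 8.28e-07, 5.13e-06 and 2.96e-06). The KO arrays of run 1 differed from the other KO arrays here, since the mean of 29 bright endoderm genes was 7.92 and 7.85 in run 1 and between 8.72 and 9.06 in runs 2 and 3, against 10.3 to 10.4 in the 6 wild-type arrays. In run 1 that mean includes genes below background, such as Pdgfra and Cubn. Apoe was higher in the KO arrays of run 1 (1632 and 1457) than in those of runs 2 and 3 (863.8 to 1086), and Krt8 was not lower there. Cubn, a receptor of visceral endoderm, had -4.45 (adjusted p = 0.014) and lost its call without KO_vehicle replicate 3 (-3.08, adjusted p = 0.0791). Of 29 basement membrane genes 9 were lower (15 adjusted over the list alone), among them the collagen chaperone Serpinh1 by -2.80 (adjusted p = 1.04e-05) and the laminin chain Lamb1 by -1.86 (adjusted p = 0.000747). That list had medians of -0.996, -0.52 and -0.29 in runs 1, 2 and 3 and a camera adjusted p = 7.37e-09 (1.31e-10 blocked), which became 0.338 with an estimated correlation.

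Cholesterol synthesis genes were lower in knockout as well. Of 20 measured members 7 were lower (14 adjusted over the list alone), with medians of -0.68, -0.60 and -0.75 in runs 1, 2 and 3 (camera adjusted p = 1.15e-12, 0.001 with an estimated correlation, 8e-16 blocked, 0.00733 with both). Msmo1, a sterol oxidase, had -1.01 (SE 0.131, adjusted p = 0.0002) and Insig1, a regulator of sterol sensing, -0.88 (adjusted p = 0.00318). Pluripotency genes went both ways, with 10 of 41 higher and 9 lower (16 and 11 adjusted over the list alone, camera adjusted p = 0.537). Dnmt3l, a cofactor of DNA methylation, was higher by 2.26 (SE 0.205, adjusted p = 4.54e-06), whereas the methyltransferase Dnmt3a was lower by -1.50 (adjusted p = 9.9e-05) and Tbx3 by -1.52 (adjusted p = 0.000222). Otx2 was higher by 2.45 (SE 0.214, adjusted p = 2.96e-06). Tdgf1 and Fgf4 were each higher by 0.98 (adjusted p = 0.000289 and 0.00134), calls that ended when arrays were centred on their medians. That centring moved the median change of bright probe sets from 0.025 to -0.19, so it lowers bright genes in general. Single genes that differed most included Srgn, a proteoglycan core protein, at -5.08 (adjusted p = 6.22e-07), the imprinted gene Mest at -4.08 (adjusted p = 8.12e-07), the testis antigen gene Fmr1nb at 3.45 (adjusted p = 1.93e-09), Aire at 3.90 (adjusted p = 1.18e-05) and the amino acid transporter gene Slc38a4, at least 19.3-fold higher (adjusted p = 1.76e-06).

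Some RA targets already differed in vehicle. Rarb and Crabp2 were at least 2.31-fold and 1.93-fold lower in knockout (adjusted p = 0.00398 and 0.00258) and Hoxa5 at least 7.84-fold lower (adjusted p = 2.25e-06). Stra8 was higher by 0.82 (adjusted p = 0.0129, 0.67, 1.01 and 0.77 in runs 1, 2 and 3). That call ended without WT_vehicle replicate 1 (0.0753), WT_vehicle replicate 2 (0.0514) or KO_vehicle replicate 3 (0.0599). It also ended when arrays were centred on their medians, with the shift of bright probe sets given above. Of the 89 genes raised by RA in wild type, 29 were lower and 5 higher in knockout vehicle, where independent lists would share 3.57 and 2.14. Of the 61 lowered genes 1 was lower and 18 higher. Both comparisons use the WT_vehicle arrays, which by chance alone would pull the raised genes the other way. The measured median was -0.49. In simulated data with no RA change it was 0.49, over as many genes with the smallest p. Genes with a real RA change need not carry a pull of that size.

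In vehicle limma called 1940 probe sets, 785 higher and 1155 lower (438 genes higher and 730 lower), and 4235 with the run as a block, which kept 1939. The count was 1126 without KO_vehicle replicate 2 and 1193 without WT_vehicle replicate 1. Without KO_vehicle replicate 3, 5 of 7 list calls were kept and 3 lists were gained, Hox genes of groups 6 to 13 downwards and p53 targets and glycolysis upwards (each 0.00698). The median change was 0.17 over all probe sets and 0.025 over bright ones, and centring each array on its median changed the split to 130 higher and 926 lower. With that centring the median over bright probe sets was -0.19.

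The comparison of knockout with wild type in RA asks how the cells differed after treatment. Several retinoid targets stood lower in knockout, but Stra8 did not (0.23, adjusted p = 0.656). Cyp26a1 was lower by -2.43 (SE 0.304, adjusted p = 9.52e-05, -2.03 to -3.19 within the runs), Crabp2 by -3.25 (adjusted p = 4.83e-05), Rarb by -1.99 (adjusted p = 5.2e-05, -1.93 to -2.08 within the runs) and Gpr50 at least 10.9-fold (adjusted p = 2.01e-05). Of 37 retinoid genes 9 were lower and 1 higher (12 and 2 adjusted over the list alone, camera adjusted p = 0.00476, 0.0106 blocked, 0.278 with an estimated correlation). Of 13 Hox genes of groups 1 to 5, 8 were lower (11 adjusted over the list alone), with medians of -1.65, -2.24 and -2.41 in runs 1, 2 and 3 (2.15e-09, 1.75e-07 blocked, 0.0539 with an estimated correlation). Hoxa5 had -4.53 (SE 0.321, adjusted p = 3.85e-07) and Hoxa3 -2.68 (adjusted p = 0.00277).

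Of 41 pluripotency genes 18 were higher and 9 lower in knockout after RA (21 and 10 adjusted over the list alone), with medians of 0.51, 0.50 and 0.44 in runs 1, 2 and 3 (camera adjusted p = 2.65e-05, 7.66e-05 blocked, 0.139 with an estimated correlation). Tdgf1 was higher by 2.29 (SE 0.132, adjusted p = 4.28e-08, 2.26 to 2.30 within the runs), Fgf4 by 2.07 (SE 0.158, adjusted p = 8.73e-07), Otx2 by 3.33 (SE 0.214, adjusted p = 1.78e-07) and Dnmt3l by 2.59 (adjusted p = 1.07e-06). Of 23 glycolysis and hypoxia genes 10 were higher (14 higher and 3 lower adjusted over the list alone), with Bnip3 at 1.53 (adjusted p = 5.67e-05), Pdk1 at 1.51 (adjusted p = 0.000591) and Pfkp at 1.10 (adjusted p = 6.88e-05). This list had medians of 0.39, 0.65 and 0.69 and a camera adjusted p = 2.38e-07 (8.37e-07 blocked, 0.0539 with an estimated correlation).

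Of 39 endoderm genes 20 were lower in knockout after RA and 1 was higher (26 and 2 adjusted over the list alone, medians -1.81, -1.19 and -1.42, camera adjusted p = 1.8e-12, 1.49e-13 blocked, 0.0539 with an estimated correlation). Krt8 had -2.46 (adjusted p = 1.5e-06), Apoe -2.31 (adjusted p = 2.58e-06) and Fabp3 -2.64 (adjusted p = 2.58e-06). Cholesterol synthesis genes were lower for 3 of 20 (7 adjusted over the list alone, 0.000282, 0.0539 with an estimated correlation), and Wnt signalling genes for 7 of 34 (7, with 1 higher, adjusted over the list alone, 0.00476 and 0.156), among them Sfrp5 at -3.08 (adjusted p = 2.72e-05) and the receptor gene Fzd7 at -1.40 (adjusted p = 1.94e-05). Camera called 13 lists here and 0 of them passed with an estimated correlation. Limma called 2225 probe sets, 998 higher and 1227 lower (594 genes higher and 779 lower), and 4466 with the run as a block, which kept 2223. The count was 1164 without WT_RA replicate 2, 1215 without WT_RA replicate 1 and 1478 without KO_RA replicate 1.

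**Figure D3:**
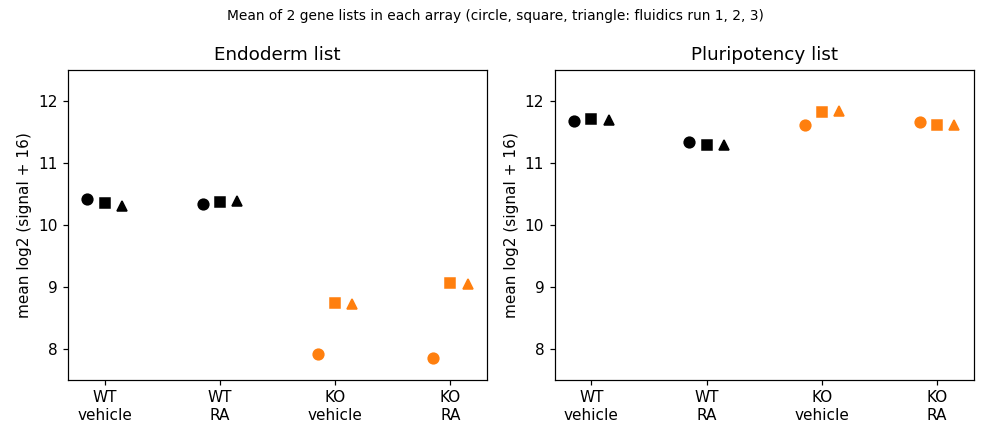
Mean log2 of signal + 16 over the measured bright genes of the endoderm list and of the pluripotency list in each of the 12 arrays by group, with circles, squares and triangles for fluidics runs 1, 2 and 3. The endoderm mean lay between 10.3 and 10.4 in the 6 wild-type arrays, between 8.72 and 9.06 in the KO arrays of runs 2 and 3, and at 7.92 and 7.85 in the KO arrays of run 1.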

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

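Tests of KO_vehicle replicate 3, of that array and of the fluidics run as explanations for smaller RA changes, and of the endoderm genes in run 1 were chosen after the results were seen, as was the run as a block, while the splits of the samples and the tests of dim signals and of starting levels were planned.

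Camera called 13 gene lists on the interaction, each against all other genes. The adjusted p values, each followed by the value with an estimated correlation, were 1.43e-10 (0.0324) for Hox genes of groups 1 to 5, 1.35e-09 (0.0324) for pluripotency, 2.07e-07 (0.0381) for glycolysis and hypoxia, 9.17e-06 (0.0198) for cholesterol synthesis, 0.000236 (0.0324) for FGF and ERK, 0.00296 (0.227) for primitive streak and mesoderm, 0.00463 (0.227) for retinoid genes, 0.00675 (0.183) for the secretory pathway, 0.00802 (0.182) for TGF-beta, BMP and Nodal, 0.00802 (0.512) for ribosomal proteins, 0.00802 (0.227) for housekeeping genes, 0.0217 (0.548) for basement membrane and 0.0388 (0.183) for Hox cofactors. The median shift was downwards for both Hox lists, retinoid and streak genes and upwards for the others. For TGF-beta, BMP and Nodal it was 0.008, with 19 genes higher and 19 lower. The median over all probe sets was -0.16, over bright ones -0.018, and over all without KO_vehicle replicate 3 -0.056. An upward call can thus stand for a fall in the other genes. Fry passed Hox genes of groups 1 to 5 and cholesterol synthesis alone (both adjusted p = 0.0179). Without KO_vehicle replicate 3 the call ended for retinoid genes (0.0609), the secretory pathway (0.325), TGF-beta, BMP and Nodal (0.288), ribosomal proteins (0.273), housekeeping genes (0.273) and basement membrane (0.704). Ribosomal proteins also lost it without WT_RA replicate 1 (0.103) or WT_vehicle replicate 3 (0.182), housekeeping genes without WT_vehicle replicate 3 (0.0657), and TGF-beta, BMP and Nodal without KO_RA replicate 1 (0.0557) or WT_RA replicate 3 (0.0783). Basement membrane lost it without WT_vehicle replicate 1 (0.0638), KO_RA replicate 1 (0.275), KO_RA replicate 2 (0.394) or WT_RA replicate 3 (0.293). Hox cofactors lost it without WT_vehicle replicate 1 (0.0638), WT_RA replicate 1 (0.061), KO_vehicle replicate 1 (0.18), KO_RA replicate 2 (0.0572), WT_vehicle replicate 3 (0.0657), WT_RA replicate 3 (0.159) or KO_RA replicate 3 (0.0819). Groups of 3 arrays are too small for a test of single outlying arrays.

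RA changes were smaller in the arrays labelled knockout, with a share of 0.508 of the wild-type change (0.779 without WT_RA replicate 2 and 0.761 without WT_vehicle replicate 3), although of 25 genes called up in knockout 13 had the larger change there. Raised dim signal on KO_vehicle replicate 3 is argued against by a share of 0.553 without it (highest of 9 combinations 0.672). Signals near background stay open. The share was 0.536 over genes whose mean over all arrays lay above 4 times the background level (highest 0.586). Such a mean can rest on the wild-type arrays: Hoxa5 had a KO_vehicle signal of 45.2, below the background level of 81.66. The test thus cannot decide. The fluidics run is argued against by the design. Each run held 1 array of every group, so a shift common to a run's arrays cancels in the RA changes. Shares within runs 1, 2 and 3 were 0.318, 0.618 and 0.612, over 93, 33 and 29 genes called in wild type on the arrays of the other runs. These repeat the comparison run by run and are not separate evidence. The lowest share was in run 1, which held KO_vehicle replicate 3 and the letter codes. Different starting levels stay open. The share was 0.483 over genes not called between genotypes in vehicle (highest 0.575) and 0.594 over those called (highest 0.846). The smaller change was thus not confined to genes called in vehicle. Genes not called can still differ, since 48% of simulated differences of 1 in vehicle were recovered. Also open is the genotype itself, untested beyond the labels, together with any other difference between the cell cultures that carry those labels. A smaller response in cells labelled as lacking the receptor is a hypothesis these values are consistent with, and limma found 0 single probe sets past the threshold for it (2084 at an unadjusted p under 0.05, where 2252 would lie if none differed), but 22 with the run as a block and 2 with KO_vehicle replicate 3 left out as well.

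KO_vehicle replicate 3 stood apart from the other arrays, with a background level of 232 against 61.6 to 99.4 and a wait of 316 minutes before the scan, and no biological explanation was tested for it. Dim probe sets had raised signal on this array. Those below background differed from the other KO_vehicle arrays by a median of 0.977 and the brightest ones by -0.109. The 2nd percentile of its signals was 18.1, against 2.2 to 3.36 on the other arrays. Whether this is the source of its standing apart stays open. The value of 0.977 fell just short of a bound of 1, which was set after the data were seen. The long wait stays open too, because the 1 other array that waited long (KO_RA replicate 1, 238 minutes) had a median of 0.109 and a single array excludes nothing. An exchange with an RA array is argued against, since it needs a KO_RA array out of place. The lowest median position of a KO_RA array between vehicle (0) and RA (1) was 0.76 (KO_RA replicate 3, lower quartile 0.611). KO_vehicle replicate 3 lay at 0.228 over 24 genes above background in the lower group (quartiles -0.214 and 0.526). Over 33 genes with a mean over all arrays above background it lay at 0.324 (quartiles -0.132 and 0.6). This exchange test replaced earlier ones that had left the exchange open, with bounds of 0.5 that were missed by the upper quartile of 0.526 and, among 5 retinoid genes, by Crabp2 at 0.525.

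Endoderm genes had a lower mean in the knockout arrays of run 1 than in those of runs 2 and 3, except that Apoe was higher there (1632 and 1457 against 863.8 to 1086) and Krt8 was not lower (477.2 and 422.1 against 327.4 to 475.4). Raised dim signal of KO_vehicle replicate 3 is argued against, since KO_RA replicate 3 lay by -1.2 from the other KO_RA arrays. The fluidics run is argued against by the wild-type arrays of run 1, which lay 0.0843 (vehicle) and -0.0466 (RA) from the other wild-type arrays of the same treatment (mean 0.0188). Wild-type cells or RNA among the knockout samples of the other runs could be a source and stay open: 15 list genes needed a median wild-type share of 0.103, but with a range from -0.0838 (Apoe) and -0.057 (Krt8) to 0.86 (Lrp2) that goes against a single share, and of 2573 abundant genes outside the list 1, Srgn, stayed under 0.0515, the bound set for this test, in all 4 arrays. Srgn had a highest ratio of 0.0373 and Hoxa5 of 0.0359 between KO_RA and WT_RA arrays, so such a share would have to be lower than Cubn and Dab2 need, while clonal or culture differences between the knockout samples were not tested.

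For the 4 contrasts of 3 against 3 arrays there are 10 splits of the arrays, too few for a share under 0.05. The real split called 211 probe sets for RA in WT, 36 for RA in KO, 1940 for KO against WT in vehicle and 2225 in RA, as many as in 1 of 10 splits each, and the highest other split called 0. For the difference of the RA changes the real count was 0, which any split reaches, so 100 of 100 drawn splits called as many and the count says nothing about chance. The highest other split called 76. It puts both KO arrays of run 1 on 1 side and turns the KO change around for the arrays of run 2. Whether a structure of the samples made its calls was not tested.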

How the results depend on the processing

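Among the alternatives, the run as a block (alone and with KO_vehicle replicate 3 left out) was chosen after the data were seen, and the cause of a change was not tested unless stated. Changes that follow from construction are those of stricter thresholds, fewer samples or 1 value per gene.

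Counts of called probe sets were 211 for RA in WT, 36 for RA in KO, 0 for the difference, 1940 for KO against WT in vehicle and 2225 in RA, and are given in this order where they moved by over 1.5 times. With the run as a block they were 949, 136, 22, 4235 and 4466, with KO_vehicle replicate 3 left out as well 1161, 109, 2, 3537 and 5180, with the title code type as a block 1122, 155, 27, 4666 and 4828, and with array weights 777, 98, 4, 3820 and 4370. Without the intensity trend they were 51, 9, 784 and 1031 (difference unchanged at 0). Median centring gave 84 for RA in WT, 1 for the difference, 1056 in vehicle and 1015 in RA. It moved the median of bright probe sets from -0.018 to 0.33 for the difference and from 0.025 to -0.19 in vehicle. An adjusted p under 0.01 gave 102, 12, 851 and 1157, an absolute log2 change of at least 1 gave 1016 in vehicle and 1227 in RA, and 1 value per gene gave 2 for the difference, 1113 and 1343. Only the groups compared gave 16 for RA in KO and 1026 in vehicle, the chip lot as a block 1 for the difference and 1211 in vehicle, and a pseudocount of 64 or leaving out dim probe sets 1 for the difference. Leaving out 1 array gave 84 to 277, 13 to 55, 0 to 1, 1126 to 2197 and 1164 to 2822.

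Of the genes called in WT in the same setting, 0 also passed the test of the difference, and 1 did with a pseudocount of 64, median centring, dim probe sets left out or the chip lot as a block, 3 with array weights, 15 with the title code type, 2 with 1 value per gene, 13 with the run as a block, 2 with KO_vehicle replicate 3 left out as well, and 0 to 1 without 1 array. The share of 0.508 was 0.436 with a pseudocount of 64, 0.574 with quantile normalization, 0.636 with median centring, 0.443 with array weights, 0.424 with the title code type, 0.577 with the chip lot, 0.648 at an adjusted p under 0.01, 0.423 with the run as a block (218 to 564 genes with a WT median of 0.88, against 26 to 93 and 1.67), 0.41 with KO_vehicle replicate 3 left out as well and 0.452 to 0.779 without 1 array. It had no value without the intensity trend, where too few genes were called. The correlation of 0.212 was 0.279 with quantile normalization, 0.337 without dim probe sets, 0.292 with array weights, 0.0662 with the chip lot, 0.331 with the run as a block and KO_vehicle replicate 3 left out, and 0.136 to 0.261 without 1 array.

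The Rarg difference in vehicle (0.163, 0.0602 to 0.317 without 1 array) turned to -0.0534 with median centring and -0.0274 with the chip lot. Centring moved the median of all bright probe sets in vehicle downwards too (0.025 to -0.19). In RA the Rarg difference (0.116) ranged from -0.0118 to 0.304 without 1 array, negative without WT_RA replicate 2. Lists called were 9, 5, 13, 7 and 13. For RA in KO 8 were called with array weights, the title code type, the run as a block, or KO_vehicle replicate 3 left out as well, 0 with an estimated correlation or fry, and 3 to 7 without 1 array. For the difference 8 were called with quantile normalization and with the run as a block and KO_vehicle replicate 3 left out, 5 with an estimated correlation, 2 with fry and 8 to 15 without 1 array. For KO against WT an estimated correlation gave 2 in vehicle and 0 in RA. Without 1 array the list counts were 8 to 11 for RA in WT, 6 to 9 in vehicle and 11 to 14 in RA. The ribosomal list turned for the difference under quantile normalization (adjusted p = 0.915), and the basement membrane list without KO_vehicle replicate 3 for RA in KO (0.625, 3.02e-09 to 0.625 over the arrays left out) and for the difference (0.704, 1.65e-07 to 0.704).

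Of 161 called results of genes considered for the text, 1790 of 1922 values under alternatives kept direction and side of the threshold, and 132 fell short of it. Without 1 array 1767 of 1932 did and 165 fell short, and 121 results passed in every such fit, 101 in every setting. None reversed, but these genes were chosen with such values in view. Over all 189 called results of the rule, 2096 of 2256 and 2064 of 2268 values kept their call and 0 reversed. Over its 300 results that were not called, 40 of 3421 and 54 of 3600 changed direction and 243 and 38 passed. Of 47 called lists 580 of 691 values and 518 of 564 without 1 array kept the call, and 12 lists did in every setting. The scan day could not serve as a block (1 day), and the difference was not run with only the groups compared, since it needs all 4. Signal near background limits what can be said of dim genes, for which only bounds are given.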

Other observations

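The tests of the starting level of RA-responsive genes and of the endoderm spread between arrays were chosen after the results were seen.

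In vehicle, single genes that were lower in knockout included Dkk1 at -3.53 (SE 0.403, adjusted p = 5.44e-05, -3.02 and -3.13 in runs 2 and 3, -2.94 without KO_vehicle replicate 3) and Sfrp2 at -2.07 (SE 0.187, adjusted p = 4.26e-06), while the Wnt list, which holds them, did not pass (4 of 34 lower and 1 higher, the same 4 and 1 adjusted over the list alone, camera adjusted p = 0.217). The Nodal antagonist Lefty2 was lower by -1.70 (adjusted p = 0.000364), Inhbb, an activin subunit, by -1.75 (adjusted p = 8.69e-06) and the ERK phosphatase Dusp4 by -2.50 (adjusted p = 3.48e-05). Ccnd2, a D-type cyclin, was lower by -1.93 (adjusted p = 1.42e-05) within a G1 list that had 5 of 30 lower and 1 higher (7 and 2 adjusted over the list alone, camera adjusted p = 0.00865, 0.122 with an estimated correlation, and 0.154 without KO_vehicle replicate 3). Neural and ectoderm genes had 4 of 32 higher (4 adjusted over the list alone, 0.0165, 0.227 with an estimated correlation), among them Stmn2, a neuronal tubulin regulator, by 2.14 (adjusted p = 0.000334). Imprinted genes went both ways, with 2 of 28 higher and 4 lower (3 and 5 adjusted over the list alone, camera adjusted p = 0.118). Among housekeeping genes Gusb was lower by -1.46 (adjusted p = 0.000621), and that list did not pass (camera adjusted p = 0.156). Tex19.1, a germline gene, was higher by 1.48 (SE 0.143, adjusted p = 8.77e-06). Kdelr3, a retrieval receptor of the secretory pathway, was lower by -2.48 (adjusted p = 2.01e-06), in a list with 3 of 26 lower (4 lower and 1 higher adjusted over the list alone, 0.00865, 0.227 with an estimated correlation, and 0.154 without KO_vehicle replicate 3).

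After RA, 2 of 20 Hox genes of groups 6 to 13 were lower in knockout (7 adjusted over the list alone, camera adjusted p = 0.017, 0.382 with an estimated correlation, 0.0509 blocked), among them Hoxa10 at least 4.05-fold (adjusted p = 0.000859). Meis1, a Hox cofactor, was lower by -2.24 (SE 0.270, adjusted p = 6.45e-05), and Snai1, a repressor of epithelial genes, by -2.36 (adjusted p = 0.000124). Ribosomal protein genes had 4 of 20 higher (6 adjusted over the list alone, 3.49e-06, 0.294 with an estimated correlation), a call that ended under quantile normalization. Targets of p53 had 2 of 22 higher (3 adjusted over the list alone, 0.0103, 0.249 with an estimated correlation). Markers of fibroblasts and muscle (0 of 18 called by limma, camera adjusted p = 0.616) and of blood (0 of 12 called, 0.616) did not pass, and endothelial markers gave 0.539 with 1 of 11 higher and 1 lower.

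Of 89 genes raised by RA in wild type, 64 had a lower estimate in KO_vehicle than in WT_vehicle. Among those called between the genotypes in vehicle, 29 were lower and 5 higher (binomial p = 3.86e-05 over genes, which are not independent). That test is against equal numbers, whereas of all genes called in vehicle 730 were lower and 438 higher. Its p value thus does not measure an excess over that split. The spread of the endoderm mean over the WT_vehicle arrays was 0.109, 3.38 times that of the pluripotency mean (0.0322). This was the test first chosen for a mixture of endoderm cells in the wild-type arrays. It cannot decide, since each spread is a range over 3 arrays and there is no reference for the ratio a mixture would give. The endoderm spread was 0.0496 over WT_RA, 0.812 over KO_vehicle and 1.21 over KO_RA arrays. The Cubn signal was 1175 to 1340 in the KO arrays of runs 2 and 3, 56.88 and 48.96 in those of run 1 and 6227 to 12040 in the wild-type arrays.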
